A study of Mus musculus with 11 samples.

How the data were processed

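The series holds bulk RNA sequencing of 4 sorted populations of mouse small-intestinal mesenchyme, with 2 libraries each, and 3 droplet single-cell libraries: 1 of sorted PDGFRA-GFP cells and 2 of whole mesenchyme. Per the labels, bulk libraries were made from 5 to 10 ng of RNA with a SMART-Seq v4 kit and sequenced on a NextSeq500. The sorted single-cell library was loaded with GFP-low and GFP-high cells at a ratio of 2:1. The labels repeat that text for the whole-mesenchyme libraries. No samples were left out, and the labels do not say whether replicates come from separate animals.

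The bulk values are counts per gene symbol, deposited by the authors as one table of unscaled whole numbers. Per the submitters' processing notes, reads were aligned with STAR to mm10; the program that counted reads, the annotation and the strand setting are not given in the sources used here. The single-cell values are UMI counts per gene and barcode, deposited as the authors' Cell Ranger matrices (version 2.1.1 for the sorted library and 3.0.2 for the whole-mesenchyme libraries, per the submitters' processing notes). Filtered and unfiltered matrices were both used. Coordinates are 1-based, from GENCODE M21 on GRCm38.

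The bulk table has 24969 gene names, of which 24802 were matched to annotated symbols. A further 26 names had been turned into dates by a spreadsheet. They held 0.131% to 0.523% of each library's counts and were left out of the tests. Library totals were 11454466 and 13908744 counts (telocytes), 14650229 and 21339417 (PDGFRAlo), 55382442 and 24664013 (blood endothelium), and 8549348 and 14838594 (lymphatic endothelium). After filterByExpr, 14893 genes were tested in edgeR 4.0.16 (R 4.3.3) with TMM scaling and quasi-likelihood F-tests. One model held the means of all 4 groups, with 4 residual degrees of freedom, a common biological coefficient of variation of 0.381 and a median prior of 5.24 degrees of freedom. P-values were adjusted by Benjamini-Hochberg and called under 0.05. A gene was specific to a population when it passed against each of the other 3 with a log2 fold over 1. CPM are counts per 1e6 scaled by TMM. When a fit left out 1 library, the lone library of its group was taken to vary like the other groups.

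Before the data were examined, 15 gene lists (BMP, Wnt and growth-factor genes among them), 19 cell-type marker lists and a rule for naming genes were written down. Lists with 4 or more tested genes were tested with limma 3.58.1 camera (log-CPM with a prior count of 2, preset correlation 0.01), adjusted over all lists of both comparisons, and also with an estimated correlation. The genes named for each bulk comparison were 6 with the largest rise and 6 with the largest fall among called genes with a mean of 20 CPM or more and no overlap between groups, BMP ligands and antagonists with 1 CPM or more in either group, 2 genes with the smallest p from each called list, and the genes of the sorted antigens. For population-specific sets, 5 genes with the highest mean CPM were named. Some genes that this rule selects are not reported here. Any other gene named was chosen after its values were seen, including the examples in the single-cell paragraphs, which were taken from the kept-out lists. A fold against a group with no count is a bound that puts 3 counts in that group.

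Single cells were kept with 500 or more genes and under 10% mitochondrial UMIs, and doublets predicted by scrublet in scanpy 1.11.5 were removed. This left 3853 of 3928 barcodes in the sorted library (37 predicted doublets) and 6116 of 6886 and 5941 of 6676 in the whole-mesenchyme libraries (120 and 102). Clusters were made by Leiden (leidenalg 0.10.2, resolution 1, 15 neighbours, 30 components, 2000 variable genes) after 99 genes of 6 lists had been kept out. Clusters were named by marker lists. The marker lists were fixed beforehand, but the rule that scores them was revised after the clusters were seen. The division at 500 CPM of Pdgfra in the sorted library and the limits of 20 CPM, 10 UMIs, 2 Pdgfra UMIs and an 8-fold lead were also set after seeing the data. Names ending in "-like" stand for marker patterns only.

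For tests between classes, UMI counts were summed per whole-mesenchyme library and class, for classes with 20 or more cells in each library, and fitted in edgeR with library as a block. Only the kept-out genes are reported, 71 of the 11051 tested. Cells were never treated as replicates. The sorted library has no replicate and was not tested; its intervals are exact 95% Poisson or binomial intervals. Shares are of all cells kept in a library, with exact 95% binomial intervals. The whole-mesenchyme libraries were compared with 50 random regroupings of their cells by a chi-square statistic per gene over 13118 genes: the median was 0.857, against a median of 0.799 and a highest value of 1.06 in the regroupings.

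Both tests were run on simulated data with known changes. Of 100 genes with a 4-fold change, 31 were called for telocytes against PDGFRAlo cells and 23 for blood against lymphatic endothelium, and of 100 with a 2-fold change, 1 in each. Of 14395 and 14424 unchanged genes, 1 and 2 were called. In the single-cell design, 98% and 99% of genes with a 2-fold change were called for the telocyte-like and CD81 stromal-like comparisons. These simulations carry 1 common spread fitted to the files, 200 changed genes and no effect of animals, so their shares are not the power in the data. Alternatives covered scaling (RLE), filtering, the replicate number as a block, DESeq2 1.42.0, a fold threshold (glmTreat), the compared libraries alone, each library left out, fry, clustering resolution, doublets, a 1000-gene limit and subtraction of free RNA. Others were chosen after seeing the data: counts restricted to genes led by the matching single-cell class, a crossed block, a narrower sorted class, class shares with the list genes left in clustering, and a 4-fold lead. Other software was Python 3.11.15, igraph 0.11.9, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.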

Results

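BMP ligands set the balance between renewal and differentiation along the crypt and villus of the small intestine, and secreted antagonists such as gremlin 1 limit where they act. The question addressed was which mesenchymal cells of the mouse small intestine transcribe these ligands and antagonists. Sorted populations were compared by bulk RNA sequencing with 2 libraries each: telocytes (GFP-high cells of the PDGFRA-H2BEGFP reporter mouse), PDGFRAlo stromal cells (GFP-low cells of the same line), CD31+LYVE1- blood endothelium and CD31+LYVE1+ lymphatic endothelium. Levels are given as CPM, with SD where given over n = 2 libraries; adjusted p-values are from edgeR quasi-likelihood tests. The labels do not say that replicates are separate animals, so the p-values measure the spread between these libraries, which may be technical.

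Telocytes and PDGFRAlo cells differed in their levels of BMP ligand transcripts, though several ligands were present in both. Bmp3, an atypical family member known to oppose other BMPs in bone, was almost restricted to telocytes, and Bmp7 and Bmp5 were also far higher there. PDGFRAlo cells instead had more Gdf6 and Gdf10. Bmp2 and Bmp6, present in both, did not pass the threshold. Bmp3 (chromosome 5, 98854415 to 98884396, plus strand) measured 495 ± 68.3 CPM in telocytes and 0.495 ± 0.700 in PDGFRAlo cells, a log2 fold of 10.09 (SE 1.16, adjusted p = 0.000671). Bmp7 (chromosome 2, 172868012 to 172940321, minus strand) measured 587 ± 27.7 against 5.23 ± 2.04 CPM, with a log2 fold of 6.82 and adjusted p = 0.0126. Bmp5 (chromosome 9, 75775364 to 75900310, plus strand) was the most abundant ligand of the bulk telocyte libraries, though not of the single-cell libraries, at 1706 ± 170.1 CPM against 127 ± 34.3 (log2 fold 3.75, adjusted p = 0.00689). Bmp4 (chromosome 14, 46383520 to 46390669, minus strand) was high in both, at 1034 ± 56.3 and 410.1 ± 29.7 CPM, and passed narrowly (log2 fold 1.33, adjusted p = 0.0354). Gdf5 was higher in telocytes but scarce, at 4.17 CPM against 0.135.

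These ligand calls were not equally secure. Without any 1 of the 4 compared libraries, Bmp4 did not pass (adjusted p between 0.127 and 0.194), nor did Gdf5 (0.0829 to 0.131), while their folds hardly moved. Bmp7 missed the threshold without PDGFRAlo replicate 1 (0.0660) or replicate 2 (0.0857), and Bmp5 without PDGFRAlo replicate 2 (0.0549). Bmp3, Gdf6 and Gdf10 kept their calls in each of these fits. Tested against a fold of 2, Bmp4 did not pass (0.340). For Bmp2 the means were 459 and 168 CPM (log2 fold 1.45, adjusted p = 0.185), with a call without the low-count filter (0.0279) or in a fit of the 4 libraries alone (0.0210). For Bmp6 the means were 169 and 110.5 CPM (log2 fold 0.61, adjusted p = 0.641). Gdf6 averaged 89.6 CPM in PDGFRAlo cells, with 23.7 in replicate 1 and 155 in replicate 2, against 1.33 in telocytes (log2 fold -6.07, adjusted p = 0.00331). Gdf10 averaged 52.1 against 2.60 CPM (log2 fold -4.34, adjusted p = 0.00247). As a list of 9 tested ligands, 5 were higher in telocytes, 2 were lower and 2 did not pass, and the counts adjusted over the list alone were the same 5 and 2. The list test placed BMP ligands higher in telocytes relative to other genes (adjusted p = 0.00929), but not with an estimated correlation (adjusted p = 0.533).

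Secreted BMP antagonists split between the populations in the same way. Gremlin 1 and chordin-like 1 were far higher in PDGFRAlo cells than in telocytes, whereas chordin, Nbl1 and Twsg1 were higher in telocytes. Pericytes were not sorted as a bulk population. Grem1 (chromosome 2, 113746164 to 113758646, minus strand) averaged 247 ± 40.6 CPM in PDGFRAlo cells and 0.985 ± 0.623 in telocytes, a log2 fold of -7.98 with adjusted p = 0.000391. Chrdl1 averaged 38.0 against 0.244 CPM (log2 fold -7.30, adjusted p = 0.00184). Nbl1, a DAN-family antagonist, was the most abundant gene of its list: 3380.0 ± 21.2 CPM in telocytes and 957 ± 203 in PDGFRAlo cells (log2 fold 1.82, adjusted p = 0.0399). Twsg1 averaged 1601 against 520.5 CPM (log2 fold 1.62, adjusted p = 0.0281), and Chrd 355 against 93.2 CPM (log2 fold 1.93, adjusted p = 0.0181). Without any 1 of the 4 libraries Nbl1 (0.118 to 0.204) and Twsg1 (0.0840 to 0.183) did not pass, and Chrd did not without telocyte replicate 1 (0.0835), telocyte replicate 2 (0.0643) or PDGFRAlo replicate 1 (0.115). Tested against a fold of 2, Nbl1 (0.153), Twsg1 (0.166) and Chrd (0.0758) did not pass. Bmper, Sostdc1, Fst, Fstl3, Dand5 and Nog did not pass, although Bmper was called lower in telocytes under 4 other settings (0.000763 to 0.0480). Of 12 tested antagonists, 3 were higher, 3 lower and 6 not past the threshold. Adjusted over the list alone, 3 were higher and 5 lower, and the list test made no call (adjusted p = 0.507). With fry in place of camera the list was called lower in telocytes (adjusted p = 0.0434).

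**Figure D1:**
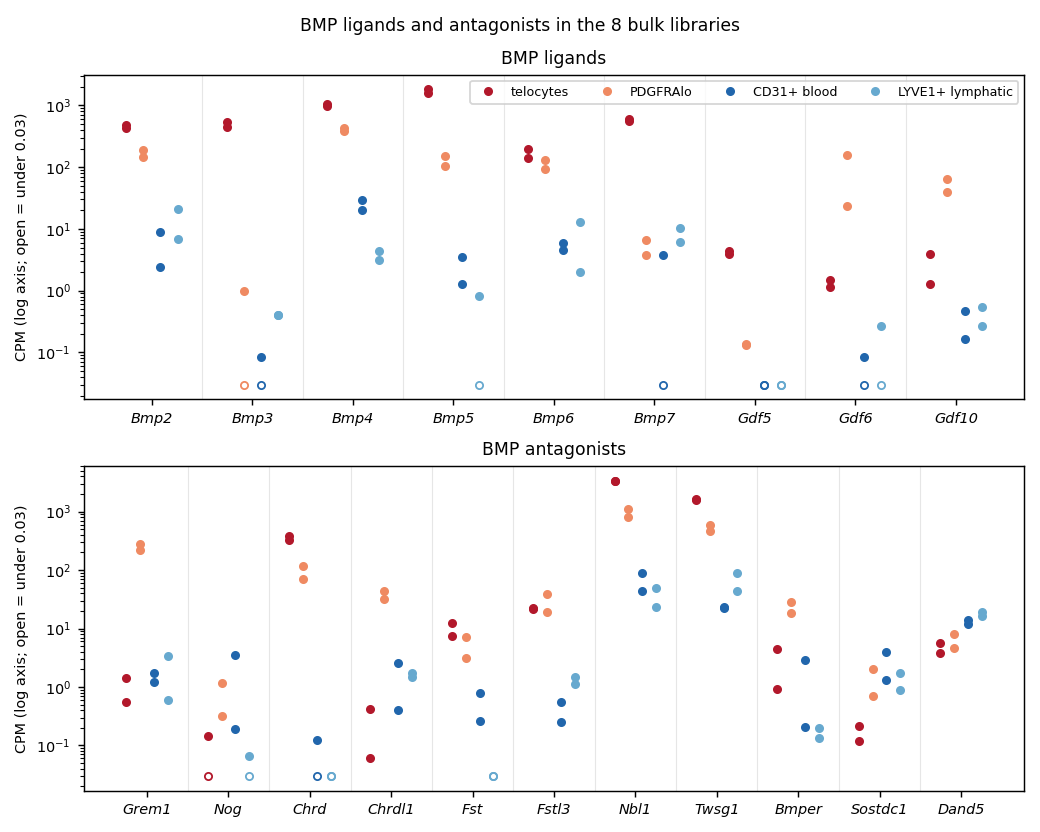
CPM (log axis) of the BMP ligands (top) and BMP antagonists (bottom) reported here in each of the 8 bulk libraries, 1 point per library, coloured by population; open points lie under 0.03 CPM. Bmp3 and Bmp7 sit above 400 CPM only in the telocyte libraries, and Grem1 averages 247 CPM in PDGFRAlo libraries against 0.985 in telocyte libraries.

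Across 14893 tested genes, 412 were higher and 1800 lower in telocytes than in PDGFRAlo cells. Among the largest rises were the synaptic vesicle gene Sv2b (298 against 1.73 CPM, log2 fold 7.44), the transcription factor genes Tbx4 (82.9 against 0.525 CPM, 7.34) and Sox6 (237 against 1.65 CPM, 7.21), and the calsequestrin gene Casq2 (284 against 2.25 CPM, 6.98). Thsd7b averaged 52.4 CPM in telocytes, with 3 counts in the PDGFRAlo libraries together. The largest falls had no count in either telocyte library, so each fold is a bound set by 3 counts over the group. Pi16, a marker of adventitial fibroblasts, was at least 559-fold lower in telocytes, the transcription factor gene Foxp2 at least 543-fold, Lrrtm3 at least 340.1-fold, the neurturin receptor gene Gfra2 at least 328-fold, Flrt2 at least 286-fold and Bche at least 245-fold. Pdgfra itself, whose reporter defined the gates, averaged 2686 ± 404 CPM in telocytes and 400.1 ± 100.1 in PDGFRAlo cells (log2 fold 2.75, adjusted p = 0.0940), and was called without the low-count filter (0.000507), with DESeq2 (0.00730) and in a fit of the 4 libraries alone (0.0109). Leaving out a library lowered the higher count to 214 (telocyte replicate 1), 158 (telocyte replicate 2) and 173 (PDGFRAlo replicate 2), and the lower count to 1148 and 889 (telocyte replicates 1 and 2). In counts simulated with 1 common spread and 200 changed genes, 31 of 100 genes with a 4-fold change and 1 of 100 with a 2-fold change were called. With so few changed genes the adjusted threshold is stricter than in the data. These shares are therefore not the power of this comparison. Genes that did not pass are still not shown to be equal.

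Several R-spondin, canonical Wnt and Notch genes were lower in telocytes than in the PDGFRAlo libraries, while non-canonical Wnt ligands and Wnt inhibitors divided. R-spondins, which strengthen Wnt signalling at the crypt base, were higher in PDGFRAlo cells than in telocytes. Rspo3 averaged 73.9 against 25.1 CPM, Rspo2 35.6 CPM and Rspo1 14.9 CPM, the last pair with 2 counts each in the telocyte libraries. Of 7 tested canonical Wnt ligands and R-spondins none was higher in telocytes and 5 were lower (list test adjusted p = 0.00217, and 0.533 with an estimated correlation). Rspo3 did not pass without any 1 of the 4 libraries (adjusted p between 0.105 and 0.277). Of 11 non-canonical Wnt ligands and Wnt inhibitors 4 were higher and 5 lower, with no call for the list (adjusted p = 0.563). With fry in place of camera it was called lower in telocytes (adjusted p = 0.0279). Telocytes had more Wnt5a (319 against 34.0 CPM) and the Wnt inhibitor gene Wif1 (133 against 1.10 CPM), and less Sfrp1 (88.4 against 4019.7 CPM) and Frzb (0.208 against 71.0 CPM). Wnt5a missed the threshold without telocyte replicate 2 (0.0520) or either PDGFRAlo library (0.0925 and 0.0859). Foxl1, the gene after which the telocytes of the mouse gut are often named, averaged 53.7 against 2.74 CPM and did not pass without telocyte replicate 1 (0.156, with its log2 fold moving from 4.31 to 3.67), telocyte replicate 2 (0.0554) or PDGFRAlo replicate 2 (0.148, with a log2 fold of 3.61). Rspo3, Wnt5a, Wif1, Sfrp1, Frzb, Foxl1 and Ogn were chosen here after their values were seen. Of 13 Notch pathway genes 7 were lower in telocytes (10 adjusted over the list alone), Notch1 and Jag2 among them (adjusted p = 0.000775, and 0.533 with an estimated correlation). Both were highest in blood endothelium (Notch1 at 93.8 CPM there, 42.3 in PDGFRAlo cells and 6.09 in telocytes; Jag2 at 39.5 in blood endothelium, 15.2 and 8.82 in the PDGFRAlo replicates and 0.516 in telocytes), whose markers were also higher in the PDGFRAlo than in the telocyte libraries. Of 30 interstitial matrix genes 10 were lower, 3 higher and 17 not past the threshold. The fibulin genes Fbln1 (12.2 against 4033 CPM) and Fbln2 (6.76 against 914 CPM) led the falls, while Ogn averaged 2775 CPM in telocytes against 485.5, a rise not called without telocyte replicate 2 (0.0530) or PDGFRAlo replicate 1 (0.0831) (list adjusted p = 0.0120, and 0.647 with an estimated correlation). Of 21 dissociation-stress genes 6 were lower, none higher and 15 not past the threshold, with Atf3 at 33.4 against 643 CPM and Dnajb1 at 116.5 against 518 CPM (adjusted p = 0.00140, and 0.533 with an estimated correlation); without telocyte replicate 1 Dnajb1 did not pass (adjusted p = 0.0841). For 2 lists the signs of the summaries differed: the smooth muscle markers had a median log2 fold of 1.43 and a mean of -0.52 with a test pointing up, and the BMP receptors and targets a median of 0.04 and a mean of -0.56 with a test pointing down, neither called.

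Markers of several other cell types were also higher in the PDGFRAlo libraries than in the telocyte libraries, but not those of pericytes (3 of 9 higher in telocytes, 1 lower) or smooth muscle (2 of 7 higher, 3 lower), whose lists were not called (adjusted p = 0.275 and 0.565). The genes of the CD81 stromal list, which mark a PDGFRAlo fibroblast subset, were lower in telocytes in 7 of 8 cases, with C3 at 23.2 against 8364 CPM and Cd81 at 6.10 against 265.5 CPM (adjusted p = 6.45e-07, and 0.533 with an estimated correlation). The same held for 10 of 11 blood endothelial markers such as Emcn and Egfl7 (adjusted p = 5.0e-07), all 10 macrophage or dendritic cell markers such as Adgre1 and Itgax (1.89e-07), all 6 B cell markers (0.00137), 8 of 13 epithelial markers such as Lyz1 and Epcam (0.000330), 6 of 9 lymphatic markers (0.00851) and 4 of 5 plasma cell markers (0.0207). With an estimated correlation each of these 6 tests had an adjusted p of 0.533. The T cell list was called lower in telocytes (0.0483, 0.0630 with the replicate number as a block, and 0.666 with an estimated correlation), with a wide spread between libraries. Gzma measured 4.55 CPM in PDGFRAlo replicate 1 and 98.9 in replicate 2; without replicate 2 its log2 fold was -1.85 and its adjusted p 0.415, and with the replicate block the adjusted p was 0.0562. Epcam (log2 fold -4.04) did not pass without telocyte replicate 2 (0.101, with a log2 fold of -3.40) or PDGFRAlo replicate 2 (0.0820, with a log2 fold of -2.46), nor in a fit of the 4 libraries alone (0.0546). Enteric neuron genes were called lower with 1 of 4 members past the threshold, Uchl1, at least 64.5-fold lower (0.0145, and 0.533 with an estimated correlation). Of the 1800 genes lower in telocytes, 1380 were found in the whole-mesenchyme single cells: 221 were highest there in a fibroblast-like class, 212 in blood endothelial-like cells, 171 in lymphatic endothelial-like cells and 493 in immune or unnamed cells. Of the 412 genes higher in telocytes, 340 were found and 199 were highest in telocyte-like cells. No such count over all tested genes is given here or below, so these numbers alone do not show an excess of any class.

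Each population also had genes higher than in all of the other 3 populations. Telocytes had 315 such genes, led by Efemp1 (3384 CPM), Nbl1 (3380.0), the endothelin receptor gene Ednrb (3365), Ogn (2775) and Smoc2 (2664). PDGFRAlo cells had 405, led by Gsn (32735 CPM), Col3a1 (31297), C3 (8364), C4b (4852) and Serping1 (4831). Blood endothelium had 905, led by Fabp4 (15729 CPM), Ifitm3 (9989), Plvap (8553) and Crip1 (8134). Lymphatic endothelium had 537, led by Jchain (115652 CPM), Cd74 (18841), Apoe (15039), H2-Ab1 (10817) and H2-Aa (9201), genes known from plasma cells, macrophages and antigen-presenting cells. Of the 391 lymphatic-specific genes found in the single cells, 102 were highest in lymphatic endothelial-like cells and 254 in immune or unnamed cells. The PDGFRA populations came from a transgenic line and the endothelial populations from C57BL/6, so these sets also carry any difference between the strains. Leaving out a library lowered the telocyte set to 170 and 116 (telocyte replicates 1 and 2) and 144 (PDGFRAlo replicate 2), and the PDGFRAlo set to 235 (telocyte replicate 2) and 262 (PDGFRAlo replicate 2). It lowered the blood set to 320 (lymphatic replicate 2) and the lymphatic set to 317 (blood replicate 2), 292 and 206 (lymphatic replicates 1 and 2).

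Endothelial cells carried little BMP ligand beside the PDGFRA populations. Blood endothelium had more Bmp4 than lymphatic endothelium, and it had more transcripts of BMP receptors and BMP-induced genes. Bmp4 averaged 25.1 ± 6.41 CPM in blood and 3.77 ± 0.963 CPM in lymphatic endothelium (log2 fold 2.75, adjusted p = 0.00257), against 1034 CPM in telocytes. Bmp2 (5.73 against 13.9 CPM), Bmp5, Bmp6 and Bmp7 did not pass, and 8 of 9 tested ligands did not pass (list adjusted p = 0.838). Of 12 antagonists, 2 were higher, 1 lower and 9 did not pass (list adjusted p = 0.680). Of the antagonists, Twsg1 was lower in blood endothelium (23.1 against 65.4 CPM, log2 fold -1.50, adjusted p = 0.0304), but not without blood replicate 1 (0.0868), blood replicate 2 (0.104) or lymphatic replicate 2 (0.182, with a log2 fold of -0.89). Without blood replicate 2, Bmp7, which has no count in blood replicate 1, and Bmp2 were lower in blood endothelium (adjusted p = 0.00459 and 0.0470), and without lymphatic replicate 2 Bmp5 was higher (0.0498). Nog passed without blood replicate 1 (0.0424) and Bmper without blood replicate 2 (0.0369). With DESeq2, Bmp5 (0.0104), Nog (0.0435), Bmper (0.0449) and Fstl3 (0.0309) also passed, and without the low-count filter Bmp7 did too (0.0188). Tested against a fold of 2, Twsg1 did not pass (0.213). Of 21 BMP receptors and targets 11 were higher in blood endothelium and none lower (13 and 0 adjusted over the list alone). Smad6, an inhibitory Smad induced by BMP, averaged 40.1 against 2.69 CPM (log2 fold 3.89, adjusted p = 0.00114), and the receptor gene Bmpr2 193 against 21.5 CPM (3.17, 0.00177). Acvrl1 and Smad7, chosen like the next 3 genes after their values were seen, were among the others, as were Eng, which did not pass without lymphatic replicate 1 (0.0538), and Id1 and Id3, which did not pass without blood replicate 1 (0.0802 and 0.0564, with log2 folds moving from 3.45 to 2.81 and from 2.86 to 2.02) or either lymphatic library (0.0636 to 0.146). The list test had adjusted p = 0.000747, and 0.533 with an estimated correlation. Markers of other cells moved with these genes: 7 of 9 pericyte and 3 of 7 smooth muscle markers and Pdgfra (16.0 against 0.740 CPM) were also higher in the blood endothelial libraries, and Jchain took 14.5% and 6.45% of the counts of the lymphatic ones. In whole-mesenchyme single cells, untested, blood and lymphatic endothelial-like cells had Bmp4 at 81.5 and 9.65 CPM of UMIs, Smad6 at 45.0 and 1.06 and Bmpr2 at 415 and 182.

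In all, 2183 genes were higher and 1239 lower in blood than in lymphatic endothelium. The median log2 fold over all tested genes was 0.12 with TMM scaling and 0.04 with RLE scaling, and the directions given here held under both. Largest among the falls were Tnfaip8l3 (0.128 against 56.0 CPM, log2 fold -8.88), Gpm6a (1.42 against 371 CPM, -8.06), Psg22 (0.107 against 26.1 CPM, -7.98), the lymphatic gene Mmrn1 (12.3 against 2396 CPM, -7.61), Slc38a4 (0.206 against 33.6 CPM, -7.41) and Pkd2l1, with 3 counts in blood endothelium and 23.4 CPM in lymphatic endothelium. Scgb3a1, which encodes a secretoglobin, averaged 3955 against 39.2 CPM (log2 fold 6.66), and the protocadherin gene Pcdh17 1207 against 13.5 CPM (6.49), although Pcdh17 did not pass without lymphatic replicate 2 (0.0590). Esrrg rested on blood replicate 2, with 44.9 CPM there and 1.06 in replicate 1; without replicate 2 its log2 fold was 2.67 and its adjusted p 0.419, and with the replicate number as a block the adjusted p was 0.0734. Defa30, Defa22 and Defa21, Paneth cell defensins of a multigene family whose copies share sequence, were also higher in blood endothelium, with Defa30 at 1272 ± 950.3 CPM. Lyve1, 1 of the sorted antigens, averaged 25.6 against 2666 CPM (log2 fold -6.70, adjusted p = 0.00319) and Pecam1, which encodes CD31, 855 against 161 CPM (2.41, 0.0225); Pecam1 did not pass without blood replicate 2 (0.0660) or without either lymphatic library (0.127 and 0.0848), nor against a fold of 2 (0.0816). Leaving out lymphatic replicate 1 or 2 lowered the higher count to 1206 or 770 and the lower count to 777 or 398, and leaving out blood replicate 2 lowered the latter to 700.

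Basement membrane and Notch genes were mostly higher in the blood than in the lymphatic endothelial libraries. Of 27 basement membrane genes 16 were higher and none lower, among them Npnt (15.2 against 0.539 CPM) and the perlecan gene Hspg2 (294 against 6.97 CPM), with a list test at adjusted p = 2.92e-06 and 0.264 with an estimated correlation. Of 13 Notch genes 8 were higher, led by the endothelial receptor gene Notch4 (102 against 3.61 CPM) and the ligand gene Jag1 (77.3 against 6.06 CPM; list 0.00239, and 0.555 with an estimated correlation). Interstitial matrix genes were higher in 13 cases and lower in 2, with Fbln2 higher and Tnxb lower (0.0183, and 0.647). Mural markers were higher as well: 7 of 9 pericyte genes (0.0320, and 0.630 with an estimated correlation), Mcam among them, while Kcnj8 was lower (5.50 against 187 CPM), and 3 of 7 smooth muscle genes, including Synpo2 and Myh11 (0.0483, and 0.641). Synpo2 did not pass without lymphatic replicate 1 (0.0658) or 2 (0.0638, with its log2 fold moving from 2.96 to 3.77), nor Myh11 without blood replicate 2 (0.163, with its log2 fold moving from 2.92 to 1.28) or lymphatic replicates 1 (0.105) and 2 (0.160). Endothelial markers divided by vessel type, with 8 of 11 blood markers such as Flt1 and Vwf higher (0.000650, and 0.555) and 6 of 9 lymphatic markers such as Fgl2 lower (5.15e-05, and 0.533). Plasma cell, B cell and macrophage markers were higher in the lymphatic libraries: all 5 plasma cell genes, Derl3 at 11.4 against 311 CPM and Sdc1 at 18.5 against 319.8 CPM (7.86e-05, and 0.533), 5 of 6 B cell genes (0.00239, and 0.533) and 5 of 10 macrophage genes, with Lyz2 at 1287 against 7834 CPM (0.00344, and 0.619), while Itgax was higher in blood endothelium (36.3 against 12.4 CPM). None of 7 T cell and none of 4 mast cell markers passed (list adjusted p = 0.878 and 0.160). Of the immune markers, Cd79a (0.0652 without blood replicate 2, 0.0589 without lymphatic replicate 1, with its log2 fold moving from -3.92 to -3.30 and -2.92), Cd79b (0.0505 without blood replicate 2) and Cd74 (0.0819, 0.0800 and 0.0784 without blood replicates 1 and 2 and lymphatic replicate 2) missed the threshold in the fits named. Against a fold of 2, Cd74 (0.111), Myh11 (0.0727) and Pdgfra (0.0556) were not called, and in a fit of the 4 libraries alone Cd74 (0.0576) and Synpo2 (0.0531) were not. Jchain alone took 14.5% and 6.45% of the counts of the lymphatic libraries, in a table that has no rows for the immunoglobulin genes Igkc, Igha and Iglc1. Pdgfra, at 16.0 against 0.740 CPM, was higher in blood endothelium, with 1.89 in replicate 1 and 30.1 in replicate 2, but not without blood replicate 2 (0.145, with its log2 fold moving from 4.35 to 1.28), lymphatic replicate 1 (0.129) or lymphatic replicate 2 (0.138). Of 2183 genes higher in blood endothelium 1812 were found in the single cells. Of these, 427 were highest in blood endothelial-like, 220 in pericyte-like, 195 in smooth muscle-like and 273 in fibroblast-like cells. A further 188 were highest in lymphatic endothelial-like cells, against the direction of the call, and 303 in immune or unnamed cells. Npnt was among the 10 leading genes of the smooth muscle-like cluster 11. Of 1239 lower, 901 were found, 182 were highest in lymphatic endothelial-like cells and 392 in immune or unnamed cells.

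The whole-mesenchyme single-cell libraries gave 6116 and 5941 cells after filtering, with the predicted doublets removed. Stromal cells were a minority. Telocyte-like cells made up 2.01% (123 cells; exact 95% binomial interval 1.67 to 2.39, counting error only) and 1.95% (116 cells; 1.62 to 2.34) of the cells. CD81 stromal-like cells made up 3.52% and 3.13%, other fibroblast-like cells 15.2% and 14.8%, smooth muscle-like cells 5.69% and 4.90%, pericyte-like cells 0.491% and 0.656%, and enteric glia-like cells 0.638% and 0.471%. Blood endothelial-like cells came to 2.60% and 2.71% and lymphatic endothelial-like cells to 1.39% and 1.35%. T cell or innate lymphoid-like cells came to 32.0% and 32.3%, plasma cell-like cells to 14.8% and 15.4%, macrophage or dendritic cell-like cells to 8.98% and 9.51%, B cell-like cells to 1.96% and 1.70%, and clusters left unnamed to 10.7% and 11.1%. The plasma cell-like share includes cluster 16 (107 and 104 cells), whose 10 leading genes hold Mki67, Top2a and other cycling genes beside the plasma cell marker Mzb1; a separate cycling class was named only with the list genes left in clustering (0.491% and 0.572%) or with 1000 genes or more per cell (0.512% and 0.543%). The labels give these libraries the same GFP sort ratio as the sorted library, yet immune cells, which lack Pdgfra, were the majority, so the shares are shares of the cells in these libraries only.

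In single cells, BMP genes were kept out of clustering, so they could be compared between classes they did not define. Among the fibroblast-like classes, Bmp3, Bmp5, Bmp7 and, in these libraries, follistatin were highest in telocyte-like cells, and gremlin 1 in CD81 stromal-like cells. These are levels, not amounts per class. In the separate libraries Bmp5 had 689 and 598 UMIs in telocyte-like cells. The CD81 stromal-like and other fibroblast-like cells together had 618 and 549. The 2 libraries differed from each other no more than random regroupings of their cells, so these p-values may reflect the sampling of cells more than differences between animals. Bmp5 measured 693 ± 74.0 CPM of UMIs (SD, n = 2 libraries) in telocyte-like and 86.0 in other fibroblast-like cells (log2 fold 2.89, adjusted p = 3.96e-25), and Bmp7 287 against 3.98 (6.02, 7.90e-25). Bmp3 measured 184 in telocyte-like cells with 1 UMI in other fibroblast-like cells. Bmp2 (397 against 161; 1.18, 3.25e-12) and Bmp4 (865 against 519; 0.62, 4.91e-06) were higher by less, and Bmp6 was lower (46.3 against 76.8; -0.85, 0.000144). Among antagonists, Fst measured 136 against 0.856, with 89.8 and 182 in the separate libraries, Nbl1 1969 against 515, Chrd 123 against 28.2 and Twsg1 461 against 218. Grem1 measured 29.0 (9.73 and 48.2 in the separate libraries) against 323 (log2 fold -3.61, adjusted p = 1.59e-12). Wnt5a (271 against 21.7), Fgf9 (113 against 0.285) and the BMP target gene Id1 (398 against 34.9) were higher too, and Sfrp1 (295 against 3240.1) and Dkk2 (23.7 against 244) were lower. Of 71 kept-out genes tested among 11051, 43 differed, 23 higher and 20 lower, and adjusted over the list alone 25 were higher and 24 lower. All 43 had the same sign in each library, which their call from these same libraries makes likely.

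CD81 stromal-like cells had more Grem1, Gdf6 and Gdf10 and less Bmp2, Bmp4, Bmp5 and Bmp6 than other fibroblast-like cells. Grem1 measured 1901 against 323 CPM (log2 fold 2.76, adjusted p = 3.90e-15), and Gdf6 (56.6 against 3.43; 4.23, 6.44e-15), Gdf10 (31.9 against 2.00; 4.11, 1.87e-10) and Chrdl1 (23.9 against 0.220) were higher as well. All R-spondin genes tested were higher, Rspo3 at 201 against 89.7, Rspo2 at 33.8 against 10.2 and Rspo1 at 19.5 against 8.58, as was Fgf7 (40.0 against 13.0). Bmp5 (1.82 against 86.0; -5.33, 4.50e-16), Bmp2 (39.0 against 161; -1.86), Bmp4 (248 against 519; -0.86), Bmp6 (23.0 against 76.8; -1.54), which was lower in telocyte-like cells too, and Ereg, an EGF-family ligand gene (59.7 against 631; -3.20), were lower, and Bmp7 had no UMI in them. Of the 71 genes, 44 differed, 24 higher and 20 lower, with 27 higher and 24 lower adjusted over the list alone. All 44 had the same sign in each library, which is likewise no separate test. Outside the fibroblast-like classes, which were not tested, Chrdl1 was highest in pericyte-like cells (454). Grem1 reached 453 in pericyte-like cells. Sostdc1 was found almost only in enteric glia-like cells (431).

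**Figure D2:**
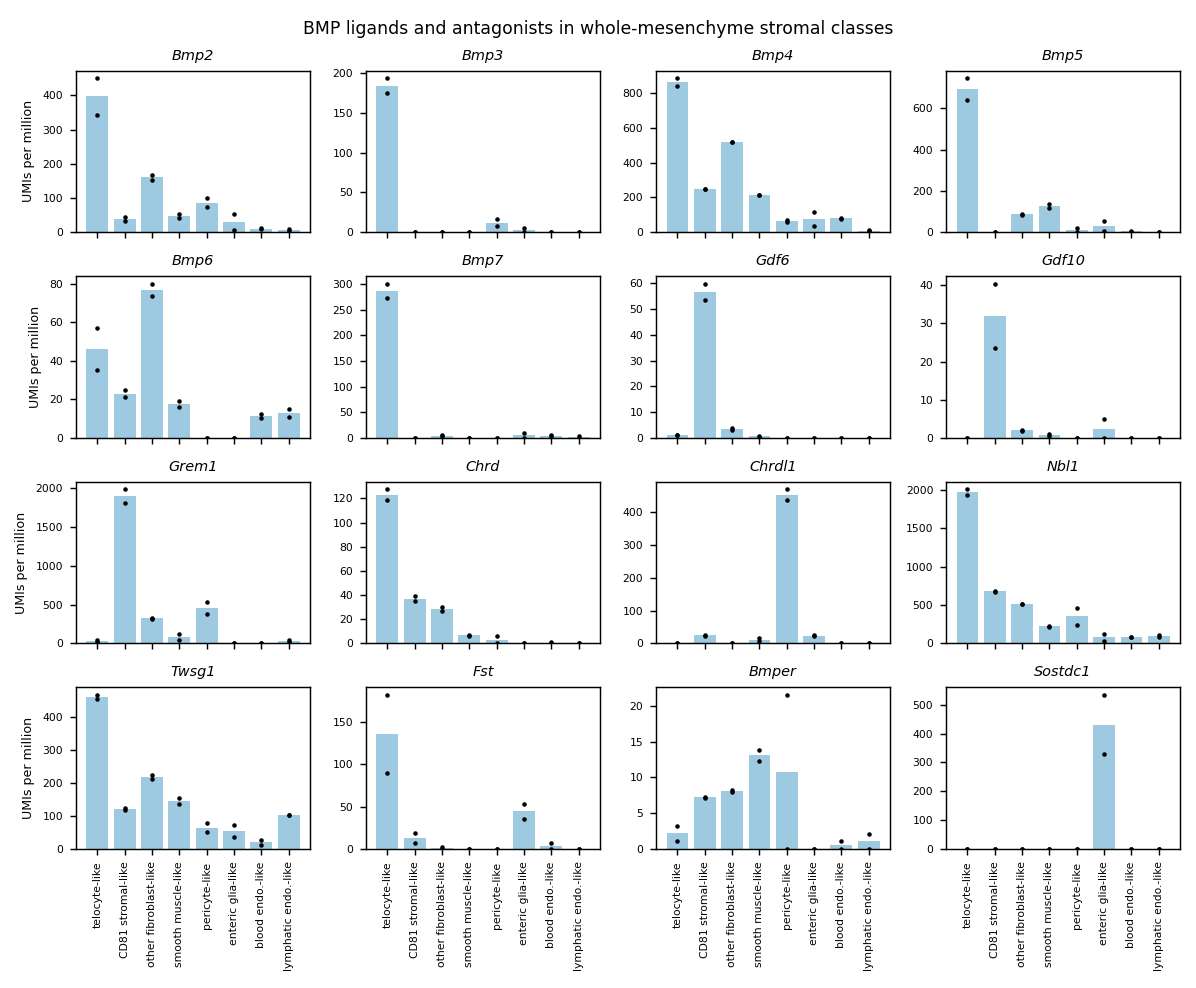
CPM of UMIs for 16 BMP ligand and antagonist genes in 8 stromal classes of the whole-mesenchyme single cells; bars are the mean of 2 libraries and points the libraries. Bmp3, Bmp5 and Bmp7 are highest in telocyte-like cells (184, 693 and 287), Grem1 in CD81 stromal-like cells (1901) and Chrdl1 in pericyte-like cells (454).

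The library of sorted PDGFRA-GFP cells had 3853 cells after filtering and no replicate, so it was described with intervals for counting error only. Its cells had been collected at a ratio of 2 GFP-low to 1 GFP-high. Clusters 5 and 6 had over 500 CPM of Pdgfra UMIs and together held 1170 cells, or 30.4% (28.9 to 31.8). Cluster 6 (371 cells) was named telocyte-like from its marker score, although none of the markers was among its 10 leading genes. The smooth muscle marker Tagln was among the 10 leading genes of clusters 5 and 6. Cluster 5 (799 cells), which scored as fibroblast, is given by number. The telocyte markers Pdgfra (1067.5 in cluster 5 and 891 in cluster 6) and Sox6 (230 and 199) were higher in cluster 5, and Foxl1 (20.7 and 39.8) in cluster 6. Both carried Bmp5 (521 in cluster 5 and 675 in cluster 6), Bmp7 (321 and 241), Bmp4 (1163 and 1574) and Bmp3 (270.04, interval 254 to 286, and 119, interval 102 to 138). Chrd was higher in cluster 5 than in cluster 6 (209 and 67.5), as was Wif1 (252 and 20.9), with intervals that did not overlap. Paneth cell transcripts also separated these clusters (Defa24 at 926.5 and 15.5, Lyz1 at 108 and 2.02). The CD81 stromal-like cluster 2 (797 cells) had Grem1 at 1165, Gdf6 at 82.2 and Chrdl1 at 54.9, while Grem1 was at 5.35 in cluster 5 and 8.77 in cluster 6. Fst, at 136 in telocyte-like cells of the whole mesenchyme, had 15 UMIs in cluster 6 (10.1, interval 5.67 to 16.7), none in cluster 5 and 33 in the CD81 stromal-like cluster 2 (8.93, interval 6.15 to 12.5), so in this library it was no higher in telocyte-like than in CD81 stromal-like cells beyond counting error. Bmp6, at 46.3 in telocyte-like cells of the whole mesenchyme, had 2 UMIs in cluster 5 and 1 in cluster 6. The matrix of the sorted library has 27999 gene rows and those of the whole mesenchyme 31053, with different barcode lists, so levels are not strictly comparable between them.

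Bulk and single-cell directions were compared for the genes of the 6 BMP, Wnt and growth-factor lists. Of 38 list genes called between telocytes and PDGFRAlo cells, 35 had enough UMIs in all 3 single-cell libraries, and 33 of them had the bulk sign in each library. The exceptions were Acvrl1 and Id4, both lower in bulk telocytes (log2 fold -1.22 and -2.06), and named after their values were seen. Acvrl1 had log2 ratios of 0.06 in the sorted library and -0.22 and 0.01 in the whole-mesenchyme libraries, and Id4 had -2.95, 0.32 and -0.73. In bulk, Acvrl1 did not pass without any 1 of the 4 libraries (adjusted p between 0.122 and 0.330), nor did Id4 without telocyte replicate 1 (0.131), telocyte replicate 2 (0.206) or PDGFRAlo replicate 1 (0.352, with a log2 fold of -0.90). Gdf5, Igf2 and Tgfa had too few UMIs. Over the gene lists together, without the marker lists, 75 of 81 genes found had the same sign in all 3 libraries.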

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

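These values were picked out because they lie in data that the comparisons did not use. None of them was tested.

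A row of the bulk table whose gene name a spreadsheet had turned into 4-Sep averaged 1261 CPM in the telocyte libraries (1237 and 1285.5) and measured 94.4 to 209 CPM in the other 6. In the whole-mesenchyme single cells, where names are intact, Sept4 averaged 762 CPM of UMIs in telocyte-like cells, 429 in pericyte-like cells and 208 in other fibroblast-like cells.

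The row for the GFP reporter in the sorted single-cell library held 46 UMIs, above the 3 that a count of 0 allows. Among barcodes with 1 to 20 UMIs, which hold free RNA, the most frequent transcript of the sorted library was Malat1 at 25039 CPM of UMIs. In the whole-mesenchyme libraries it was Igkc, at 112217 and 111227.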

How the results depend on the processing

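No named gene that was called in the main fit or in an alternative changed direction, and no called list did so with fry. Some list calls ended with fry. In telocytes against PDGFRAlo cells this held for the T cell list (fry adjusted p = 0.208). In blood against lymphatic endothelium it held for interstitial matrix (0.0580), smooth muscle (0.102) and macrophage or dendritic cell (0.0651). Other lists gained a call with fry. Lower in telocytes were BMP antagonists (0.0434), non-canonical Wnt ligands and Wnt inhibitors (0.0279) and growth factors (0.0285). Chemokines and cytokines (0.0285), basement membrane (0.0434) and fibroblast markers (0.0478) were lower there too. Higher in blood than in lymphatic endothelium were growth factors (0.0213), Hedgehog (0.0225), enteric neuron (0.0285) and mast cell (0.0294). Between blood and lymphatic endothelium 3 lists without a call pointed down with camera and up with fry: BMP ligands (fry adjusted p = 0.602), T cell (0.941) and sex-linked genes (0.941). Under RLE scaling, without the low-count filter and with the replicate number as a block, every count of called genes stayed within 1.5 times its value. With the replicate block, telocytes had 407 genes higher and 1724 lower, and blood endothelium 2145 and 1193. Replicates with the same number in different populations shared little deviation (correlations from -0.103 to 0.195), so the numbers need not mark pairs. The cause of each change below was not tested unless stated.

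With a fold threshold of 2, 203 genes were higher in telocytes, and 934 were higher and 469 lower in blood endothelium; the threshold asks for more by construction. In fits of the 4 compared libraries alone, 640 genes were higher in telocytes. DESeq2 called 638 genes higher in telocytes and 1932 lower in blood endothelium. With an estimated correlation, 0 lists were called in telocytes against PDGFRAlo cells and 0 in blood against lymphatic endothelium, against 14 and 11.

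Leaving out 1 library at a time gave 158 to 291 genes higher and 889 to 1533 lower in telocytes, and 770 to 1954 higher and 398 to 1010 lower in blood endothelium. Population-specific genes ranged from 116 to 347 (telocytes), 235 to 408 (PDGFRAlo), 320 to 813 (blood) and 206 to 488 (lymphatic). Of 51 called named genes between telocytes and PDGFRAlo cells 14 lost their call in at least 1 of these fits, and of 39 between blood and lymphatic endothelium 11 did.

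Restricting the counts to genes highest in the matching single-cell class, chosen after seeing the data, left 199 higher and 221 lower in telocytes, 427 higher and 182 lower in blood endothelium, and 177, 176, 255 and 102 specific genes for telocytes, PDGFRAlo, blood and lymphatic endothelium; fewer genes are counted by construction.

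Mean shares moved by more than the SD of the libraries as follows. With doublets kept they were 3.61% for CD81 stromal-like, 14.7% for other fibroblast-like, 2.74% for blood endothelial-like, 1.45% for lymphatic endothelial-like, 31.7% for T cell or innate lymphoid-like and 15.55% for plasma cell-like cells, and 6.37% for unnamed clusters, since a mast cell class was then named. With 1000 genes or more per cell they were 2.07% for telocyte-like, 15.4% for other fibroblast-like, 1.40% for lymphatic endothelial-like, 1.24% for B cell-like and 8.58% for macrophage or dendritic cell-like cells. With the list genes left in clustering, tried after seeing the data, they were 32.5% for T cell or innate lymphoid-like and 14.6% for plasma cell-like cells and 10.6% for unnamed clusters. The numbers of differing kept-out genes stayed between 43 and 45 under all settings. Leaving out 1 whole-mesenchyme library leaves no residual degrees of freedom, so it gives no test.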

Other observations

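The tests of the immune-transcript and endothelial-transcript patterns below were chosen after the result they measure had been seen, and those of the dissociation stress pattern before.

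Some cytokine and growth factor genes, picked after their values were seen, differed between the populations. Most members of their lists did not pass, and the lists were not called with camera. In telocytes against PDGFRAlo cells 1 of 24 chemokines and cytokines was higher and 8 lower, and 1 of 21 growth factors higher and 6 lower; in blood against lymphatic endothelium the counts were 2 and 8, and 3 and 1. Il6 averaged 216 CPM in PDGFRAlo cells and 1.48 in telocytes (log2 fold -7.20, adjusted p = 0.000702). Fgf9 averaged 138 CPM in telocytes and 4.39 in PDGFRAlo cells (4.97, 0.00120), and Fgf7 the reverse, at 2.98 against 51.1 CPM (-4.10, 0.00313). Lymphatic endothelium had the most Il7 (136 CPM, with 1.53 in blood endothelium) and Il33 (489.5 and 12.6 CPM), and blood endothelium had more Cxcl12 (907 against 66.0 CPM). The potassium channel genes Kcnj8 (772 against 7.81 CPM) and Abcc9 (712 against 11.3 CPM), markers of pericytes, were higher in telocytes than in PDGFRAlo cells.

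Plasma-cell and macrophage transcripts were higher in the LYVE1+ than in the CD31+LYVE1- libraries. Expression by lymphatic endothelial cells is unlikely to account for this: over the 10 plasma-cell and macrophage markers called in this direction (Itgax, called the other way, was left out), single cells with Cdh5 and with Prox1 or Mmrn1 (95 and 86 cells, whatever their cluster) had a median log2 ratio of -4.85 to the LYVE1+ libraries (-4.04 and -5.66 in the separate single-cell libraries), against 1.74 and 2.595 for 7 lymphatic markers. A first comparison, with Cdh5 cells lacking both genes, was set aside because those cells held plasma-cell transcripts (Jchain at 10762 and 18521 CPM). Immune cells or their RNA in the LYVE1+ libraries stay open. Of 12 genes led 8-fold by plasma cell-like or macrophage or dendritic cell-like cells and on no marker list, 75% were lower in blood endothelium. Their median log2 fold was -1.36. Both genes led by plasma cell-like cells were lower, and a further 4, Igkc and Igha among them, have no row in the bulk table. Of 10 genes led by macrophage or dendritic cell-like cells, 7 were lower. In that class C1qa was among the 10 leading genes of cluster 18 (304 cells). It was not among those of clusters 12, 15 and 23 (512, 182 and 116 cells). The count therefore does not separate macrophage from dendritic cell genes. With a 4-fold lead, tried because the 8-fold lead left few genes, 32 of 42 were lower. These were all 7 led by plasma cell-like cells (median log2 fold -3.87) and 25 of 35 led by macrophage or dendritic cell-like cells (-0.72). Jchain reached 167013 and 64290 CPM in these libraries against 60709 in plasma cell-like cells, so no share of cells can be read from it.

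Endothelial transcripts were higher in the PDGFRAlo than in the telocyte libraries. Expression by PDGFRAlo fibroblasts is unlikely to account for this. Over the 10 called blood endothelial markers, whole-mesenchyme cells outside the telocyte-like class with 2 or more Pdgfra UMIs lay below the PDGFRAlo libraries. They were 534 and 491 cells, whatever their cluster. Their median log2 ratios to those libraries were -3.94 and -3.57, and their highest -2.38 and -2.25. Telocyte-like cells had a median log2 ratio of -0.21 to these other cells (-0.28 and -0.15 in the separate libraries), against a bulk median of -5.10. That ratio decides nothing alone, because most markers measured a few CPM on both sides and a constant added to both levels shrinks it. Plvap measured 18.4 and 21.7 CPM in the other cells with Pdgfra. It measured 19.4 in the 2683 cells of the sorted library outside clusters 5 and 6, and 1800.3 and 623 in the PDGFRAlo libraries. Telocytes had 42.6 and 29.5, and blood endothelium 7945 and 9161. Endothelial cells or their RNA in the PDGFRAlo libraries could account for the pattern: 100% of the 20 genes led 8-fold by blood endothelial-like cells and on no marker list were lower in telocytes (median log2 fold -5.24). With a 4-fold lead, tried after the first result, 37 of 38 genes were lower. The 2683 sorted cells include cluster 3 (293 cells), left unnamed, whose 10 leading genes hold Plvap, Selp and Madcam1. Their pooled Plvap level is therefore not one shared by all of them.

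Dissociation stress genes lay lower in the telocyte than in the PDGFRAlo libraries (median log2 fold -1.04), with 6 of 21 called and no list call with an estimated correlation (adjusted p = 0.533). Within each whole-mesenchyme library, where all cells shared 1 dissociation, the median log2 ratio of telocyte-like to other fibroblast-like cells was -0.34 (-0.35 and -0.33 in the separate libraries). Different handling of the sorted cells and lower expression by telocytes cannot be told apart by this value.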
